A study of Mus musculus with 6 samples.

How the data were processed

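Total RNA from 3 biopsies of healthy skin and 3 skin tumors of FVB/N mice was labelled with Cy3 and measured on 1-colour Agilent arrays with 62976 spots each, per the labels' protocols and the file headers. Per the file headers, the deposited intensity values were extracted with Agilent Feature Extraction 10.7.3.1, which subtracts a fitted background from each spot, and all 6 arrays lay on 1 slide. The deposited series table holds log2 values whose rank on each array equals that of the deposited median spot signal without background subtraction (Spearman correlation 1 on every array) and whose column medians are close (6.33 to 6.35), as after quantile normalization. The submitters' processing notes name limma, with no version given, and the centring and background handling of that table are not given in the sources used here. The labels do not say whether the biopsies came from different mice, so p-values measure the spread between these samples.

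The main values were log2 processed signals minus each array's 75th percentile over the 59305 spots that were not controls. Spots flagged as outliers were left out, which removed 180 of 55681 probes, spots of 1 probe were averaged, and saturated spots did not occur. Probes well above background on at least 3 of the 6 arrays were kept (34283), and the probe with the highest mean over all arrays stood for its gene, which gave 24756 features. Of 6416 genes with several probes, 73 had probes called in opposite directions. Probes were named through their accessions in the RefSeq table of assembly GRCm38.p6, used for names only (15275 features by accession, 1015 by symbol, 178 by synonym), and 8288 features kept the array's own name without a matched symbol. Probe positions are those of the array's annotation (mm9). A probe not well above background on any array of a group has only a bound there. It was computed from the mean of the bright group and, for the dim group, the mean over arrays of the higher of the probe's own signal and the lowest signal well above background. It is written as "at least N-fold" and holds for these background-subtracted signals only. Where some arrays of a group were well above background, their number is given.

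Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), without a block. Gene lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 36 lists. Before the data were examined, the lists, their tests, the alternative settings and the rule for named genes were fixed, apart from 1 alternative, without the healthy skin 3 and tumor 1 arrays together. Tests of explanations for the muscle and fat genes, the balance of directions and the hair genes were chosen after the results were seen. The rule took genes with a symbol, past the test, with all 3 arrays of a group on one side of all 3 of the other: the 10 largest rises and 10 largest falls with at most 2 per symbol stem, 2 members per called list in its direction, up to 2 members per other list, and a panel of 10 genes. Other list members are named where they were the exceptions to a list's direction or made up a small count, chosen after their values were seen. Some genes that the rule names are not reported here. The number of arrays limits the precision.

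The scripts were tested on simulated data with the real features' means and spreads, in which 200 of 24756 features were changed between tumor and healthy skin. The 29 oxidative phosphorylation genes were also shifted by a log2 size of 1, as a test of the lists. Noise was drawn separately for each feature, so the number of false calls does not carry over to correlated genes. Among the 200, 0 of 50 features changed by a log2 size of 1 were recovered. At larger sizes, 20 of 50 were recovered at 2, 30 of 50 at 3 and 40 of 50 at 4, and 4 unchanged features were called. The simulation gave 94 calls and the real data 6420. The Benjamini-Hochberg adjustment is stricter when fewer features differ, so these rates do not give the power of the real test. The alternatives were quantile, median and spike-in scaling, normexp background correction with an offset of 50, the authors' deposited values, no detection filter and a stricter one, the mean of probes or every probe by itself, a variance trend, array weights, the replicate number or slide row as a block, the arrays of slide row 2 alone, leaving out each array, camera with an estimated correlation or on ranks, fry, and treat.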

Results

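Gene expression was measured in biopsies of mouse skin on 1-colour microarrays, with 3 arrays of healthy skin and 3 arrays of skin tumors. All mice were female and of the inbred strain FVB/N. Tumors were raised by painting the skin with DMBA, a polycyclic hydrocarbon mutagen, and then repeatedly with the tumor promoter TPA (also called PMA), a phorbol ester that activates protein kinase C, for 6 weeks and, after another dose of DMBA, for 14 more weeks. Healthy skin was treated with acetone, the solvent. The labels give an RNA integrity number of 9 and 0.2 µg of RNA for every sample. On each array, between 48.7% and 65.4% of the 59305 spots that were not controls were well above background. The tumor 1 array had the lowest share and the highest median background, 85 intensity units against 23 to 26 on the other arrays, and the healthy skin 3 array was the dimmest, with a 75th percentile signal of 242 against 525 to 897 on the others. Across the 24756 features tested, the arrays of 1 group correlated more closely (Pearson r of 0.937 to 0.971 within healthy skin and 0.959 to 0.966 within tumors, across features, which are not independent replicates) than arrays of different groups (0.821 to 0.894).

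The comparison asked which genes differ between tumors and healthy skin. Only the tumor group had been painted with DMBA and TPA, and no treated skin without a tumor was measured. Effects of the tumor and of the treatment therefore cannot be told apart in any result below. In tumors, 27 of 29 stress keratins and alarmins and 16 of 21 matrix remodeling genes were higher, and 24 of 24 skeletal muscle genes and 16 of 19 adipocyte genes were lower. As whole lists, these had adjusted p = 0.211, 0.293, 0.278 and 0.408 with an estimated inter-gene correlation. Among the largest rises was that of Ltf, the iron-binding neutrophil and mucosal protein lactoferrin (probe on chromosome 9, positions 110942873 to 110942932, mm9), which was not well above background on any healthy skin array and was at least 4227-fold higher in tumors (adjusted p = 0.000158). Among the largest falls was that of Cyp2g1, a cytochrome P450 (probe on chromosome 7, positions 27606111 to 27606170, mm9), whose signal was 303-fold lower in tumors (log2 fold change -8.24 ± 1.15 SE, and -6.80 without tumor 2, adjusted p = 0.00326). Of the 24756 features, 6420 differed (25.9%; limma, Benjamini-Hochberg adjusted p under 0.05), 2553 of them higher and 3867 lower in tumors. Of these, 6196 had an estimated difference of at least 2-fold, while a test against a log2 fold change of 1 (treat) called 1666.

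The count depended on single arrays and the balance of directions on the scaling and the detection filter. Without healthy skin 2 the number of differing features was 4059 (1481 higher), all of them past 2-fold, and without tumor 2 it was 3840 (1375 higher, 2465 lower), also all past 2-fold. The number of higher features was 1681 without healthy skin 1 and 1609 without tumor 1, and without the healthy skin 3 and tumor 1 arrays together, an alternative chosen after seeing the data, 5157 features differed. Higher features made up 39.8% of the called ones with the arrays aligned at their 75th percentile, 50.7% with median scaling and 70.9% with scaling to the spike-in RNA, under which 2686 features differed. With the 75th percentile scaling their share was 48.4% among probes well above background on all 6 arrays. The median log2 fold change of all features was -0.16 in the main scaling, 0.01 with median scaling and 0.73 with spike-in scaling, so each fold change below is relative to the array's upper signals and not to the amount of RNA per cell. Fold changes of genes near background in a group also depend on the background correction. The log2 fold change of Ltf was 13.08, with a bound of 12.05, but 10.01 with normexp correction. Over all features, fold changes from the authors' deposited values had a slope of 0.773 on those used here. "At least" therefore holds only for the background-subtracted signals used here. Where a gene was well above background on some arrays of a group, its fold includes signals near background and is less certain. Slide row 1 held no tumor array, so the fits with the slide row as a block and on slide row 2 alone are the same contrast, healthy skin 3 by itself against the 3 tumors.

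Of 36 gene lists, 20 differed by camera with a preset inter-gene correlation of 0.01, 11 of them higher and 9 lower in tumors. With the correlation estimated from the arrays, none of the lists passed (0 at an adjusted p under 0.05, 5 at an unadjusted p under 0.05, lowest adjusted p = 0.164), and fry called 18 lists. With the preset correlation, camera also called 10 to 25 lists in the other splits of the 6 arrays into 3 and 3. Each side of those splits holds more arrays of either tumor or healthy skin, so part of the group difference remains. They therefore do not show how many lists would be called without a difference. Estimating the correlation from 6 arrays leaves that test little power. With it the skeletal muscle list, with 24 of 24 members lower, had an unadjusted p = 0.0523 by camera. The absence of calls with it therefore does not show that the lists do not differ. Since the calls depend on the correlation assumed, a call of a whole list carries little weight here. The counts of members describe each list, but members of some lists vary together and are not independent evidence. The mean correlation of members within groups ran from -0.045 for Notch pathway genes to 0.696 for hair shaft and inner root sheath genes. Over all 24756 features, 2553 were called higher and 3867 lower, and each count is to be read against those shares. Each list below has the number of members past the test over all features and, beside it, the number adjusted over the list alone.

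**Figure D1:**
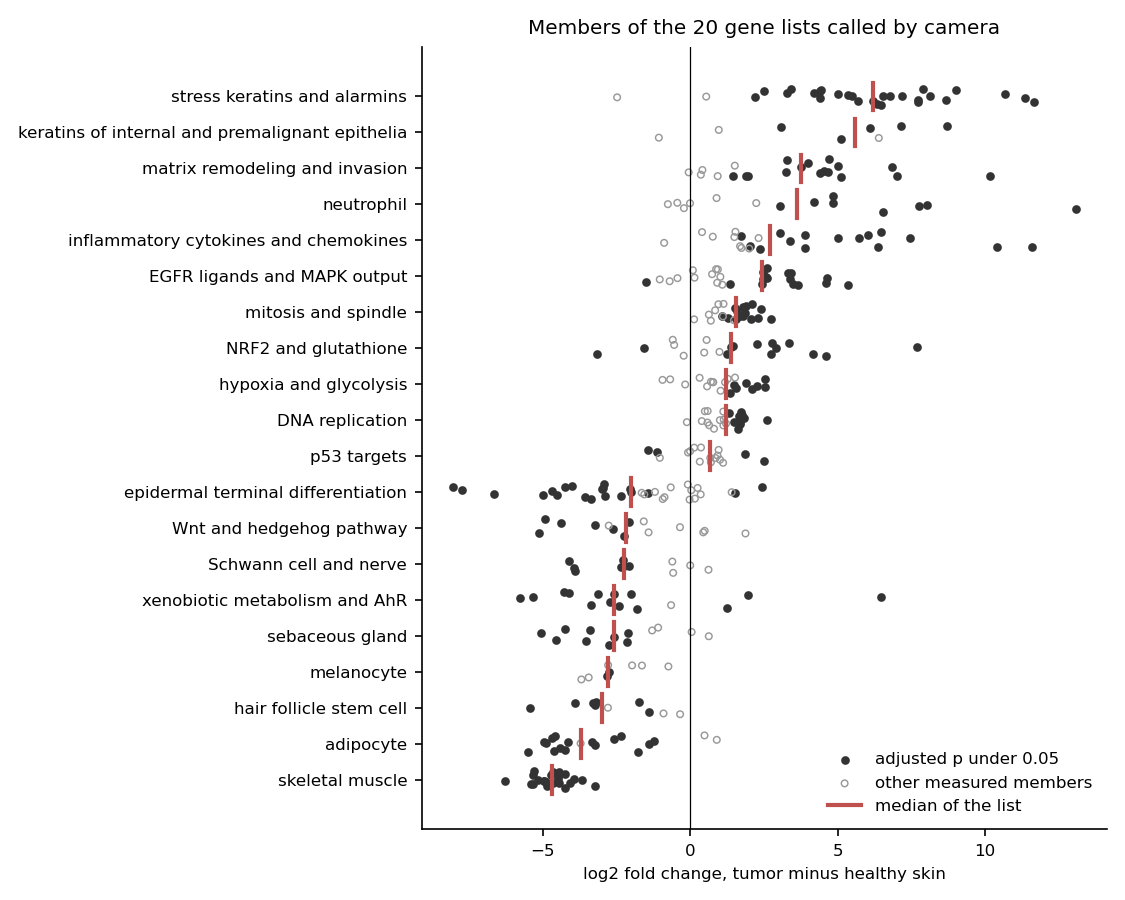
Log2 fold change (tumor minus healthy skin, 3 arrays each) of every measured member of the 20 lists called by camera with the preset correlation, with filled points past an adjusted p under 0.05 and a bar at each list's median. The medians run from -4.70 for skeletal muscle genes to 6.20 for stress keratins and alarmins.

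Stress keratins and alarmins, the genes that wounded and inflamed epidermis switches on, gave 27 of 29 members higher in tumors (27 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 6.20. The list's adjusted p was 2.06e-19, and adjusted p = 0.211 with an estimated correlation. Krt6a, a keratin of activated keratinocytes, rose 73.5-fold (log2 signal 1.53 ± 1.13 SD in healthy skin and 7.73 ± 0.27 in tumors, n = 3 each, limma adjusted p = 0.000734), and S100a8, a subunit of calprotectin, rose 40.7-fold (limma adjusted p = 0.0011). Sprr3, a cornified-envelope precursor, was not well above background in healthy skin and was at least 549-fold higher in the mean of the tumors. The tumors differed (log2 signal 7.16, 4.81 and 0.83), and the bound does not hold for tumor 3 by itself. Sprr2f rose 3199-fold and Lce3a 1642-fold, each well above background on 1 of 3 healthy skin arrays. The Sprr2, Lce, Stfa, Serpinb3 and Krt6 families have members of similar sequence, so a probe of one member may also have bound its relatives, and the values of single members are uncertain. Among keratins of internal and premalignant epithelia, 5 of 8 members rose (6 adjusted over the list alone). The median was 5.59, with adjusted p = 0.000797 by camera and adjusted p = 0.317 with an estimated correlation. Krt18, a keratin of simple epithelia, rose 140-fold (limma adjusted p = 0.000993), and Krt4, a keratin of the mouth and esophagus, was not well above background in healthy skin and at least 120-fold higher in the mean of the tumors. Its tumor values lay far apart (log2 signal 6.27, 2.07 and -2.14), so that bound does not hold for tumor 3 either, and the list's median was 5.02, 4.38 and 0.23 in the tumors. The log2 fold change of Krt4 ran from 5.05 to 10.82 over the alternatives, and its call was lost in both fits with healthy skin 3 by itself.

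Matrix remodeling and invasion genes were higher in 16 of 21 members (17 adjusted over the list alone). The median was 3.77, or 3.28 with bounds in place of fitted values, with adjusted p = 6.29e-12 by camera and adjusted p = 0.293 with an estimated correlation. Over the alternatives this median ran from 1.92 to 4.66. Mmp13, a collagenase, rose 1161-fold (log2 fold change 10.18, but 6.78 with normexp correction) and Spp1, the secreted phosphoprotein osteopontin, rose 129-fold, and each was well above background on 1 of 3 healthy skin arrays, so these folds are uncertain. Inflammatory cytokines and chemokines were higher in 15 of 24 members (17 adjusted over the list alone). The median was 2.70, or 2.58 with bounds, with adjusted p = 1.29e-11 by camera and adjusted p = 0.164 with an estimated correlation. Cxcl5 and Cxcl3, both chemokines that attract neutrophils, were at least 815-fold and at least 331-fold higher, with neither well above background in healthy skin. With normexp correction their log2 fold changes were 7.68 and 6.26, below these bounds of 9.67 and 8.37. Neutrophil genes were higher in 8 of 14 members (10 higher and 1 lower adjusted over the list alone). The median was 3.63, or 2.46 with bounds, with adjusted p = 2.74e-05 by camera and adjusted p = 0.317 with an estimated correlation. It was 1.33 with normexp correction and 2.15 with the authors' deposited values, both below the median with bounds. Retnlg rose 262-fold and was well above background on 1 of 3 healthy skin arrays. Among probes well above background on all 6 arrays, which leaves out genes undetected in healthy skin, the neutrophil list was not called (median -0.11, adjusted p = 0.875).

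EGFR ligands and genes of the MAPK output were higher in 15 and lower in 1 of 27 members (18 higher and 1 lower adjusted over the list alone). The median was 2.44, with adjusted p = 4.42e-08 by camera and adjusted p = 0.211 with an estimated correlation. It was 1.52 with normexp correction and ran from 1.21 to 3.33 over all alternatives. Hbegf, an EGFR ligand, rose 40.9-fold (log2 signal -0.44 ± 0.19 SD in healthy skin and 4.92 ± 0.54 in tumors, n = 3 each, limma adjusted p = 0.000294), and Dusp4, a phosphatase that MAPK signaling induces, rose 25.1-fold. Btc, another ligand of the receptor, was the member that fell (log2 fold change -1.49). Mitosis and spindle genes were higher in 15 of 23 members (20 adjusted over the list alone). The median was 1.57, with adjusted p = 3.1e-09 by camera and adjusted p = 0.408 with an estimated correlation. Top2a was 6.67-fold and Plk1 5.27-fold higher. DNA replication genes were higher in 11 of 23 members (16 adjusted over the list alone). The median was 1.21, with adjusted p = 1.99e-07 by camera and adjusted p = 0.408 with an estimated correlation. Ccne1 was 6.08-fold and Rrm1 3.53-fold higher, with the Rrm1 call lost in 5 of 21 alternatives. The groups overlapped in the median of the DNA replication list, which was 2.08 in healthy skin 3 and 1.81 in tumor 3.

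Among metabolic lists, hypoxia and glycolysis genes were higher in 8 of 20 members (8 higher and 1 lower adjusted over the list alone). The median was 1.23, with adjusted p = 0.000117 by camera and adjusted p = 0.424 with an estimated correlation. That median ran from 0.67 to 2.12 over the alternatives. Pgk1, a glycolytic kinase, rose 5.8-fold, on a probe that the array's annotation places on chromosome 3, while the gene lies on the X chromosome, so the signal may come from another copy of its sequence. Pfkl, a phosphofructokinase subunit, rose 5.74-fold. NRF2 and glutathione genes were higher in 11 and lower in 2 of 19 members (12 and 2 adjusted over the list alone). The median was 1.37, with adjusted p = 0.000148 by camera and adjusted p = 0.211 with an estimated correlation. The glutathione transferases Gsta4 and Gsta1 rose 206-fold and 24.5-fold, while Gstm1, another of them, and the malic enzyme Me1 fell (log2 fold changes -3.15 and -1.56). Xenobiotic metabolism and AhR genes were lower in 11 and higher in 3 of 15 members (the same numbers adjusted over the list alone). The median was -2.58, with adjusted p = 0.00692 by camera and adjusted p = 0.317 with an estimated correlation. Cyp1a1, the P450 that the aryl hydrocarbon receptor induces, was 54.1-fold lower and well above background on 1 of 3 tumor arrays, Cyp2b19 was 40.6-fold lower, and Aldh1a3, a retinaldehyde dehydrogenase, was 87.6-fold higher. The xenobiotic list was called in 19 of 23 alternatives. It was not called among probes well above background on all 6 arrays (adjusted p = 0.0582), nor with healthy skin 3 by itself against the tumors (adjusted p = 0.0884 with the slide row as a block). The p53 targets were called as higher (adjusted p = 0.0486, and adjusted p = 0.568 with an estimated correlation; median 0.68), yet 2 of 17 members rose and 2 fell (5 and 2 adjusted over the list alone). The kinase Plk2 and the microtubule-binding, cell-cycle regulated Gtse1 rose 5.67-fold and 3.6-fold, the death receptor Fas and the stress-induced Sesn1 fell (log2 fold changes -1.43 and -1.13), and the list was called in only 7 of 23 alternatives. Its call was lost, among others, with quantile normalization (adjusted p = 0.117), median scaling (adjusted p = 0.0523), spike-in scaling (adjusted p = 0.0754), the authors' deposited values (adjusted p = 0.118) and fry (adjusted p = 0.132).

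Skeletal muscle genes fell in 24 of 24 members (24 adjusted over the list alone), with a median log2 fold change of -4.70 and an interquartile range of -5.00 to -4.40. The list's adjusted p was 6.79e-16, and adjusted p = 0.278 with an estimated correlation. Pvalb, a calcium buffer of fast muscle, was 78.1-fold lower in tumors (limma adjusted p = 0.000652), and Eno3, the muscle enolase, was 42.2-fold lower (log2 signal 7.17 ± 0.17 SD in healthy skin and 1.77 ± 0.26 in tumors, n = 3 each, limma adjusted p = 0.000173). Outside the list, Mstn, the inhibitor of muscle growth myostatin, and Dhrs7c, a dehydrogenase of the sarcoplasmic reticulum, were 122-fold and 117-fold lower, and they were well above background on 1 and 2 of 3 tumor arrays. Adipocyte genes fell in 16 of 19 members (17 adjusted over the list alone). The median was -3.72, with adjusted p = 4.83e-06 by camera and adjusted p = 0.408 with an estimated correlation. Car3, a carbonic anhydrase abundant in fat and muscle, was 45.1-fold lower and the adrenergic receptor Adrb3 31.2-fold lower. Schwann cell and nerve genes fell in 7 of 11 members (7 adjusted over the list alone). The median was -2.26, with adjusted p = 0.00323 by camera and adjusted p = 0.211 with an estimated correlation. S100b, a calcium-binding protein of glial cells, was 15.4-fold lower.

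Epidermal terminal differentiation genes were lower in 18 and higher in 2 of 33 members (19 and 3 adjusted over the list alone). The median was -1.997, with adjusted p = 0.000797 by camera and adjusted p = 0.568 with an estimated correlation. Lce1m and Flg2, both genes of the cornified layer, were 265-fold and 212-fold lower, and the higher members were Tgm1, a transglutaminase, and Cnfn, cornifelin (log2 fold changes 1.53 and 2.43). This list was called in 19 of 23 alternatives, and was not called by fry (adjusted p = 0.0645) or with healthy skin 3 by itself against the tumors (adjusted p = 0.128 with the slide row as a block). Sebaceous gland genes fell in 9 of 13 members (10 adjusted over the list alone). The median was -2.59, with adjusted p = 0.000944 by camera and adjusted p = 0.408 with an estimated correlation. The wax synthase Awat2 was 33.7-fold lower, and the fatty acid hydroxylase Fa2h was 23.3-fold lower. Awat2 was well above background on 1 of 3 tumor arrays. The sebaceous list was called in 21 of 23 alternatives, and had adjusted p = 0.0515 with the slide row as a block, where healthy skin 3 stands by itself. Hair follicle stem cell genes fell in 7 of 10 members (7 adjusted over the list alone). The median was -2.995, with adjusted p = 0.000457 by camera and adjusted p = 0.278 with an estimated correlation. The transcription factor Lhx2 was 43.2-fold lower and the growth factor Fgf18 15.1-fold lower. Wnt and hedgehog pathway genes fell in 7 of 14 members (7 adjusted over the list alone). The median was -2.16, with adjusted p = 0.0129 by camera and adjusted p = 0.451 with an estimated correlation. Gli1, a transcription factor that hedgehog signaling induces, was 35.3-fold and the Wnt inhibitor Wif1 30.3-fold lower. The Wif1 call was lost in 4 of 20 alternatives. The list was called in 18 of 23 alternatives, and not without the healthy skin 3 array (adjusted p = 0.0549). Among probes well above background on all 6 arrays, which leaves out genes undetected on some tumor arrays, its median was 0.05 and the call was lost (adjusted p = 0.624). Melanocyte genes fell in 2 of 8 members (4 adjusted over the list alone). The median was -2.78, with adjusted p = 0.0175 by camera and adjusted p = 0.56 with an estimated correlation. The members that fell were the transcription factors Sox10, which Schwann cells also express, and Mitf, 7.02-fold and 6.84-fold lower. The list was called in 18 of 23 alternatives, and not without the healthy skin 1 array (adjusted p = 0.0708) or by fry (adjusted p = 0.076). Healthy skin 2 lay at the level of the tumors, with melanocyte medians of 1.31, -2.47 and 0.47 in healthy skin and -2.44, -3.77 and -1.86 in tumors. Adrb3, S100b, Wif1, Cd3g and Cd207 were each well above background on 2 of 3 tumor arrays.

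Genes outside the lists were also among the largest falls. Hamp2, a hepcidin gene, was 136-fold lower, Carns1, the carnosine synthase, 113-fold lower, Serpinb7 111-fold lower and the soluble receptor gene Il22ra2 110-fold lower, the last well above background on 1 of 3 tumor arrays. The potassium channel gene Kcnj16 was not well above background on any tumor array and was at least 27.9-fold lower. Among the largest rises outside the lists, Ppbp, a platelet chemokine, and Psca, a prostate stem cell antigen, rose 1391-fold and 1186-fold, each well above background on 2 of 3 healthy skin arrays, and Tmprss11a, a transmembrane serine protease, was at least 263-fold higher and not well above background in healthy skin.

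A panel of 10 genes was chosen for its role in skin carcinogenesis. Hras, the oncogene that DMBA commonly mutates, had a log2 fold change of 1.43 ± 0.50 SE and did not pass the test (limma adjusted p = 0.0709), and of its 2 probes 1 had this direction. It was called in 5 of 21 alternatives, among them normexp correction, array weights and the replicate block, and also in both fits that rest on healthy skin 3 by itself. Trp53 did not pass either (0.64 ± 0.31 SE, limma adjusted p = 0.162), and was called in 1 of 21 alternatives. Cdkn2a, which encodes the tumor suppressors p16 and Arf, rose 237-fold (log2 signal -4.15 ± 0.93 SD in healthy skin, where 2 of 3 arrays were well above background, and 3.74 ± 0.80 in tumors, n = 3 each, limma adjusted p = 0.000414). Krt13, a keratin used as a marker of progressing papillomas, rose 8.4-fold, Krt8 34.4-fold (log2 fold change 5.10, but 3.79 without tumor 2) and the cyclin gene Ccnd1 6.12-fold, with the Ccnd1 call lost in 6 of 21 alternatives, while Krt1, a keratin of suprabasal epidermis, was 7.74-fold lower (limma adjusted p = 0.0427), a call lost in 12 of 21 alternatives.

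**Figure D2:**
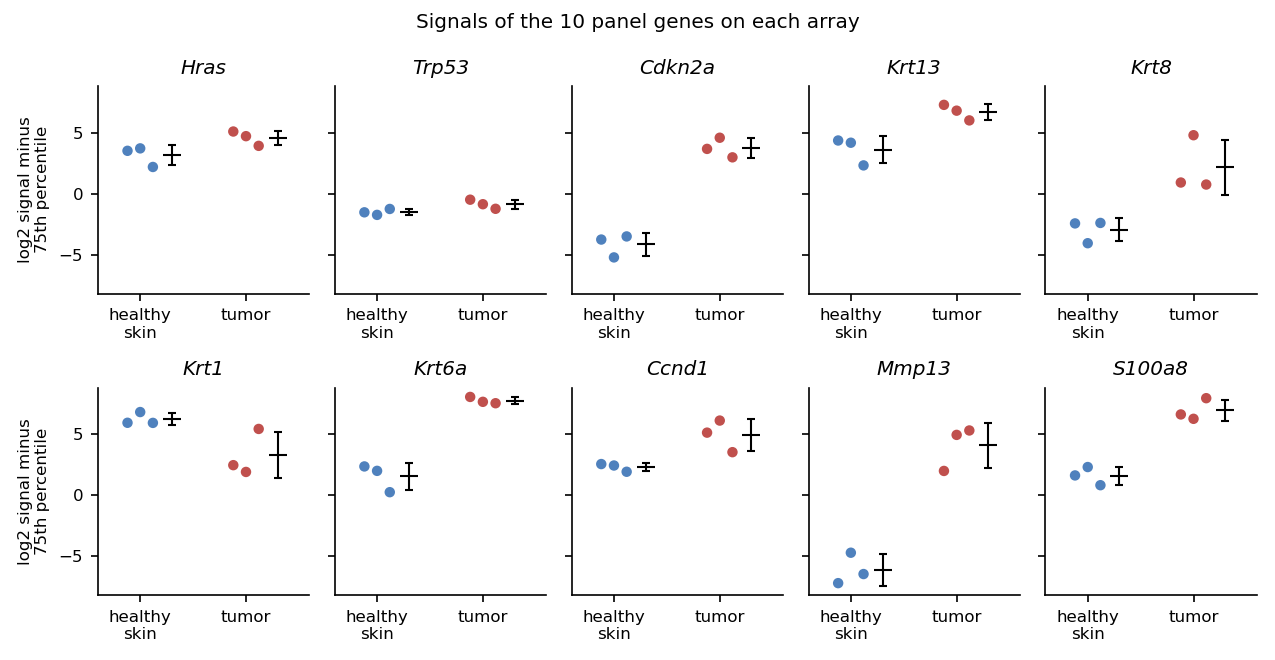
Log2 signal minus the array's 75th percentile for the 10 panel genes, each point an array and each black mark the mean with its SD (n = 3 per group). The Cdkn2a means were -4.15 in healthy skin and 3.74 in tumors, and the Trp53 means were -1.50 and -0.86.

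The remaining 16 lists were not called. Macrophage genes had 4 higher and 2 lower of 17 members (6 and 2 adjusted over the list alone; adjusted p = 0.06). Arg1, an arginase, rose 217-fold and the lectin receptor Clec7a 46.2-fold. Their log2 fold changes ran from 6.68 to 9.545 and from 4.56 to 6.42 over the alternatives. The macrophage list, with a median of 0.90, was called as higher in 9 of 23 alternatives, among them the fits without healthy skin 1 (adjusted p = 0.00618), healthy skin 2 (adjusted p = 0.0355), tumor 1 (adjusted p = 0.00697) or tumor 2 (adjusted p = 0.0437), while its median was -0.08 without healthy skin 3. Of the 9 alternatives, 2 are the same contrast of healthy skin 3 by itself against the tumors (median 2.13, adjusted p = 0.00498 with the slide row as a block). T and NK cell genes had 3 lower of 16 members (3 adjusted over the list alone; adjusted p = 0.13), with Cd3g 13.8-fold and Cd3e 4.64-fold lower. The Cd3e call was lost in 5 of 21 alternatives, and the list was called as lower without tumor 2 (adjusted p = 0.0267). Dendritic and Langerhans cell genes had 1 higher and 2 lower of 14 members (1 and 2 adjusted over the list alone; adjusted p = 0.781), with Cd207, the Langerhans cell lectin, 38.9-fold lower and the integrin gene Itgax 9.05-fold higher. B and plasma cell genes had 2 higher and 1 lower of 8 members (2 and 1 adjusted over the list alone; adjusted p = 0.274). Mast cell genes had 2 higher and 2 lower of 10 members (2 and 2 adjusted over the list alone; adjusted p = 0.988), with a median of -1.16. Tpsab1, a mast cell tryptase, was not well above background in healthy skin and at least 8.76-fold higher in tumors. With normexp correction its log2 fold change was 1.52, below this bound of 3.13. Endothelial genes had 1 higher and 1 lower of 16 members (1 and 1 adjusted over the list alone; adjusted p = 0.781), Emcn 3.23-fold higher and Vwf 3.7-fold lower. Dermal fibroblast and collagen genes had 2 higher and 2 lower of 18 members (2 and 2 adjusted over the list alone; adjusted p = 0.271), with Dpt and Dcn 7.64-fold and 5.78-fold lower and the collagen genes Col1a1 and Col5a1 higher (log2 fold changes 1.73 and 1.76). Dpt lost its call in 8 of 21 alternatives, and the list, with a median of 0.56, was called as higher without tumor 1 (adjusted p = 0.0325) and without both healthy skin 3 and tumor 1 (adjusted p = 0.0266). Basal keratinocyte and hemidesmosome genes had 4 higher and 1 lower of 15 members (5 and 1 adjusted over the list alone; adjusted p = 0.0816), with the integrin subunit Itga3 7.43-fold higher. The list was called as higher in 7 of 23 alternatives, among them array weights (adjusted p = 0.0179), the mean of probes (adjusted p = 0.0341), and the fits without healthy skin 3 (adjusted p = 0.0435) or tumor 1 (adjusted p = 0.0369).

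Circadian clock genes had 7 lower and 1 higher of 16 members (8 and 2 adjusted over the list alone; adjusted p = 0.121), with Hlf 5.75-fold and Cry2 4.58-fold lower. This list was called as lower in 3 of 23 alternatives: by fry (adjusted p = 0.00198), among probes well above background on all 6 arrays (adjusted p = 0.0116) and without healthy skin 3 (adjusted p = 0.0457). Interferon response genes had 1 higher and 2 lower of 21 members (0 adjusted over the list alone; adjusted p = 0.412), and were called as lower without tumor 2 (adjusted p = 0.0437). Cholesterol and fatty acid synthesis genes had 2 higher and 3 lower of 21 members (2 and 3 adjusted over the list alone; adjusted p = 0.412), with the elongase Elovl6 10.4-fold lower. Notch pathway genes had 3 higher and 2 lower of 14 members (3 and 2 adjusted over the list alone; adjusted p = 0.482), with a median of 0.05 and a mean of -0.17. Mesenchymal transition genes had 1 lower of 12 members, Cdh2, whose call was lost in 6 of 21 alternatives (0 adjusted over the list alone; adjusted p = 0.769; median 0.06 and mean -0.03). Of 29 oxidative phosphorylation genes, 0 passed limma's test (0 adjusted over the list alone; adjusted p = 0.281). Common reference genes had 3 higher of 16 members (3 adjusted over the list alone; adjusted p = 0.0816), Pgk1 on the same doubtful probe, Gusb and Hprt. The Gusb call was lost in 10 of 21 alternatives, and the list was called as higher in 7 of 23, among them quantile normalization (adjusted p = 0.0299) and the authors' deposited values (adjusted p = 0.00764).

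Hair shaft and inner root sheath genes had 2 lower of 29 members (0 adjusted over the list alone; adjusted p = 0.734), the homeobox genes Hoxc13 and Msx2, 16.1-fold and 3.09-fold lower. The Hoxc13 call was lost in 7 and the Msx2 call in 14 of 21 alternatives. The signal of the hair genes differed within both groups. The list's median log2 signal was 4.39 in healthy skin 1, -1.36 in healthy skin 2 and -1.53 in healthy skin 3, and it was 1.79 in tumor 1, -2.73 in tumor 2 and 1.51 in tumor 3. The list was called as higher in tumors without healthy skin 1 (adjusted p = 0.000902) and on the arrays of slide row 2 alone, where healthy skin 3 stands by itself (adjusted p = 0.00575). Over the alternatives its median ran from -1.71 to 3.04, and it was below 0 without healthy skin 2, healthy skin 3, tumor 1 or tumor 3, so no direction is claimed.

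**Figure D3:**
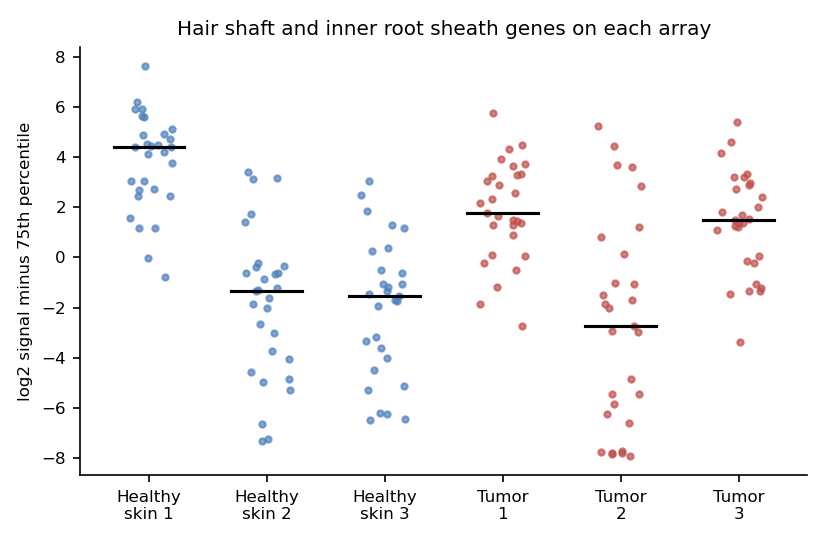
Log2 signal minus the array's 75th percentile for the 29 measured hair shaft and inner root sheath genes on each array, with each point a gene and each bar the median. The medians were 4.39, -1.36 and -1.53 in healthy skin and 1.79, -2.73 and 1.51 in tumors.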

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

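Probes that the detection filter left out were not part of any comparison. Among them, 1015 probes were well above background on 2 tumor arrays and no healthy skin array, against 481 on 2 healthy skin arrays and no tumor array. Of the 1015, 953 were detected in tumors 2 and 3, the arrays other than the one with the highest background. No explanation was weighed for this.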

How the results depend on the processing

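No named gene or list reversed its direction of call under any alternative, although among probes well above background on all 6 arrays the medians of the neutrophil (-0.11) and Wnt and hedgehog (0.05) lists changed sign and both calls were lost. The number of differing features, here called genes with or without a symbol, was 6420 in the main setting. It moved by over 1.5 times with spike-in scaling (2686), with no detection filter (3920 of 36019 features tested), with array weights (9857), and without healthy skin 2 (4059) or tumor 2 (3840). It lay between 3840 and 5458 over the 6 fits without single arrays. Genes lower in tumors numbered 782 with spike-in scaling, 2444 with no filter, 2399 with probes well above background on all 6 arrays, and 2465 to 3236 without single arrays, and genes higher in tumors numbered 1476 with no filter, 4229 with array weights and 1375 to 2222 without single arrays. Genes past 2-fold, 6196 in the main setting, numbered 2686 with spike-in scaling, 3920 with no filter, 1666 by treat against a log2 fold change of 1, and 3840 to 5075 without single arrays. Gene lists numbered 20 to 22 without single arrays and 0 with camera's correlation estimated from the arrays. Without the 2 doubted arrays, an alternative chosen after the data were seen, 5157 genes and 19 lists differed. The labels state no pairing of tumors and healthy skins, and the correlations of same-numbered deviations were 0.103, 0.129 and -0.083. With 3 arrays per group, these correlations cannot show whether the samples are paired. With the replicate block 5470 genes differed. Slide row 1 held no tumor, so the row as a block (8437 genes) and the arrays of slide row 2 alone (5017 genes) both compare healthy skin 3 by itself with the tumors, and neither corrects the full comparison for slide position. The causes of these shifts were not tested, except that no filter raised the number of tests and that leaving out arrays left fewer samples. Of the 20 called lists, 13 stayed called under every alternative but the estimated correlation. Of 87 named genes that passed the test, 46 lost their call in none of the alternatives that tested them, and 27 of the 87 lost their call on the arrays of slide row 2 alone, with 1 healthy skin array. Signal over background limits the dim genes, and the lowest signal well above background ranged from -5.94 to -3.64 on the normalized log2 scale between arrays.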

Other observations

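The tests of muscle and fat genes, of the balance of directions and of hair genes were chosen only after the results were seen, and those of chromosomes 7 and 6 and of other splits were fixed before. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For the number of differing features 1 split gave as many, the real one, with 6420 features against a highest other of 0. For those past 2-fold it was also 1, with 6196 against 0. For gene lists 3 splits gave as many as the real one, which called 20 against a highest other of 25, so camera's calls with the preset correlation also come from groupings that mix tumors and healthy skin. Those groupings keep part of the difference between tumors and healthy skin, so they do not show how many lists would be called without it.

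Skeletal muscle and adipocyte genes were lower in tumors. The choice of scaling is argued against as the cause, since the highest median of either list over the scalings was -2.83. In 93.0% of the 43 measured members all tumors lay below all healthy skins, which restates the pattern. Less muscle and fat in the tumor biopsies and lower expression within those cells both predict it and cannot be told apart, since no cells were counted. The interquartile range of the log2 fold changes was -5.00 to -4.40 for muscle genes and -4.62 to -2.06 for adipocyte genes.

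More features, here called genes, were lower than higher in tumors in the main scaling. Of the 4559 called features with a gene symbol 44.0% were higher, and of the 1861 called features without one 29.5% were. With spike-in scaling the share of higher genes among those called was 70.9%, so the balance depends on the scaling. In the main scaling the share was 48.4% among probes well above background on all 6 arrays, so the balance also depends on the detection filter. Changing from one array factor to another moves the fold changes of all genes alike, and this does not show which scaling is right. Without tumor 1, the array with the highest background, the share was 37.3%. The features had been filtered with that array included, so this share does not exclude an effect of its background through the detection filter. The labels give 0.2 µg of RNA for every sample, so none of the scalings can show a difference in RNA content between the tissues. What the shift with spike-in scaling reflects was not tested. The spike-in shift leans on healthy skin 3, which had the lowest 75th percentile (log2 7.92, against 9.04 to 9.81 on the others). It also had the highest mean spike-in signal (log2 13.09, against 12.46 to 12.83). Spike-in scaling without that array was not run.

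Hair shaft and inner root sheath genes varied within both groups. Array-wide noise is argued against, since the list's median SD within groups, 3.65 on the log2 scale, lay above all of 10000 random lists matched on mean expression (percentile 100), although marker lists vary more than random ones and the next list, the melanocyte genes, had 1.80. The members' deviations correlated with each other across arrays at a mean of 0.696, against 0.014 in the median random list, but other lists came close, with 0.66 for interferon response, 0.642 for mast cell and 0.629 for mitosis genes, so the correlation is not particular to hair genes. Biopsies differing in growing hair follicles is a candidate explanation, and the site and hair cycle stage of the biopsies are not in the labels.

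Gains of chromosomes 7 and 6, known in tumors of this model, were tested as hypotheses. The median log2 fold change of the 1344 chromosome 7 genes minus that of the other autosomes was 0.054 (95% bootstrap interval -0.030 to 0.117 over genes), which does not decide between a small gain and none. For the 819 chromosome 6 genes it was -0.067 (-0.194 to 0.043), which lay below the 0.1 set beforehand for a gain. These intervals cover the spread over genes only: over all autosomes the same difference ran from -0.128 on chromosome 4 to 0.218 on chromosome 13 and 0.189 on chromosome 1, for which no gain was proposed, so the chromosome 6 value counts only weakly against a shared gain. In a biopsy that mixes cell types, a gain in part of the cells could stay below these limits, and the chromosome 7 value of 0.054 differed between tumors (0.135, -0.068 and 0.013).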
